A study of Homo sapiens with 12 samples.

How the data were processed

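Gene expression was measured by RNA sequencing in Caco-2 cells, a human colorectal adenocarcinoma line that takes on enterocyte features in culture. Per the labels, the 12 libraries form 4 groups of 3. Cells were kept for 48 h in a nutrient-rich growth medium (1 g/L glucose, 2 mM glutamine, 20% serum) or a nutrient-depleted one (0.1 g/L glucose, 0.2 mM glutamine, 1% serum). In each medium they received vehicle or 100 nM bafilomycin A1, an inhibitor of the vacuolar proton pump that acidifies lysosomes. Total RNA was depleted of ribosomal RNA before a stranded library preparation, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

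The deposited table of each sample gives an estimated count of reads for 54553 genes, per the file headers, and 5.08% of these values are not whole numbers. A series-wide table deposited by the authors holds whole-number counts for 13518 genes. These are the genes with at least 10 reads in all 12 libraries, and every value lies within 0.5 of the sample's own estimated count. The submitters' processing notes name DRAGEN and the GRCh38 build, with no version and no role. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes, and of close copies such as histone, annexin A8, AKR1C and CEACAM genes, cannot be assigned with certainty. Gene symbols were used as deposited, and 51557 of them matched the RefSeq annotation of GRCh38.p14, the source of the coordinates.

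The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 18047 genes, and libraries were scaled by TMM factors. Each comparison used edgeR 4.0.16 (R 4.3.3) with robust dispersion estimates and quasi-likelihood tests, in 1 fit of all 12 libraries with a mean per group and 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Standard errors were derived from the log2 fold change and the F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. The 5 comparisons were bafilomycin A1 against vehicle in each medium, depleted against rich medium in each treatment, and the interaction, the bafilomycin A1 response in depleted medium minus that in rich medium.

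A total of 35 gene lists (pathways, complexes and cell type markers) was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run beside it. Members were counted as rising or falling after adjustment over all genes, and again adjusted over the list alone. The lists, the tests, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined, except where a choice is said to have been made after seeing the data.

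Named genes were taken by rule. In each comparison these were the 5 highest and 5 lowest log2 fold changes among called genes with a mean of at least 5 CPM and groups that did not overlap (a condition not applied to the interaction), leaving out clone, locus and small RNA names. Up to 3 called members with at least 1 CPM and the largest fold changes came from each of the 8 lists with the smallest camera p. Up to 2 members with the smallest adjusted p came from other lists described, and a fixed panel was tested in every comparison, of which some members and values are left out of the text. CA9, a panel member, did not pass the filter and has no value.

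The test was checked on simulated negative binomial counts with each gene's mean and dispersion and each library's size, with 100 genes changed 2-fold and 100 changed 4-fold. For bafilomycin A1 in rich medium it recovered 51% of the 2-fold and 91% of the 4-fold changes. For the interaction it recovered 18% and 84%. False calls made up 5.96% and 8.11% of all calls in these simulations. The simulated groups shared 1 spread per gene and held no library that stood apart. Where the real groups differ in spread, these shares need not hold. Alternatives covered DESeq2 1.42.0 size factors, the DESeq2 test, no low-count filter, fits of only the 6 libraries compared, the replicate number as a block, the series-wide count table, removal of mitochondrial, ribosomal and small RNA genes, a minimum fold of 1.5, and leaving out each library in turn. Fits without 2 libraries that stood apart were added after seeing the data.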

Results

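The 12 libraries held between 12969814 and 51649213 reads assigned to genes. Replicate 1 of the rich-medium vehicle group was the shallowest at 12969814 reads with 17485 genes detected, while the other 11 libraries held at least 33859998 reads. Ribosomal RNA made up 1.36% of the reads in that library and up to 9.10% in the others. No library was a copy of another. The median difference between gene length and effective length, a measure that grows with fragment length, was 181, 194 and 207 in the depleted-medium bafilomycin A1 libraries and 212 to 236 in the other 9. Gene length correlated with the log2 fold change at rho = 0.103 for bafilomycin A1 in depleted medium and 0.117 for depletion under bafilomycin A1. It was 0.0814 for the interaction, and -0.0123 and 0.0300 for rich bafilomycin A1 and depletion. The first principal component (43.7% of the variance) ran from rich-medium vehicle to depleted-medium bafilomycin A1 libraries. The shallow rich-medium vehicle replicate 1 lay at -142 on it, and replicates 2 and 3 of that group at -53.3 and -63.4. Part of that share of the variance thus rests on the shallow library. Replicate 3 of the rich-medium bafilomycin A1 group stood apart from its group. Its Spearman correlation across genes was 0.979, 0.975 and 0.986 with depleted-medium vehicle replicates 1, 2 and 3. With replicates 1 and 2 of its own group it was lower, at 0.973 and 0.972.

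**Figure D1:**
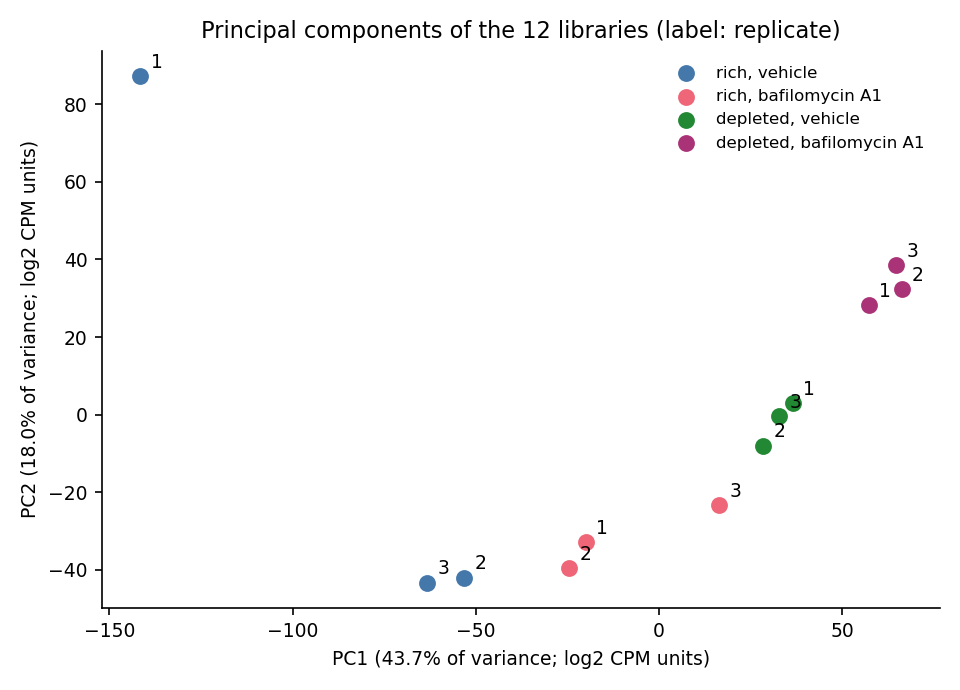
Principal components of the log2 CPM values of the 12 libraries, with PC1 (43.7% of the variance) on the horizontal and PC2 (18.0%) on the vertical axis; each point is 1 library, coloured by group and numbered by replicate. Rich-medium vehicle replicate 1 lies far from the other libraries, and rich-medium bafilomycin A1 replicate 3 lies between its group and the depleted-medium vehicle libraries.

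The first comparison asked which transcripts changed when lysosomal acidification was blocked in rich medium. Among the lists 29 of 34 mitosis and 20 of 35 ribosome biogenesis genes fell, and 14 of 40 autophagy and 11 of 24 hypoxia response genes rose. DDIT4, an inhibitor of mTORC1 signalling (chromosome 10, 72273924 to 72276036, GRCh38.p14), rose from 15.2 ± 6.34 to 117 ± 17.7 CPM (SD, n = 3; log2 fold change 2.94, SE 0.26, adjusted p = 3.5e-05). YPEL2 rose from 1.44 ± 0.474 to 11.2 ± 2.05 CPM and BIRC7, an inhibitor of apoptosis, from 0.255 ± 0.224 to 2.41 ± 0.668 CPM. NOX1, a superoxide-producing oxidase of colon epithelium, fell from 50.3 ± 11.2 to 13 ± 4.3 CPM (log2 fold change -1.95, SE 0.33, adjusted p = 0.0027), and LIN28A, NPPB, TAGLN and FJX1 fell by log2 values of -1.90, -1.75, -1.72 and -1.70. In all, 1109 genes rose and 862 fell among 18047 tested.

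The other 2 genes taken for a high fold change were KLHDC7B (log2 fold change 4.61, SE 1.14) and LAMP3, a lysosome-associated membrane protein (2.90, SE 0.67). In replicates 1, 2 and 3 of the treated group KLHDC7B stood at 1.57, 1.91 and 19.8 CPM and LAMP3 at 9.10, 6.43 and 42.8 CPM, and without replicate 3 the log2 fold changes were 2.46 and 1.58. Leaving out any 1 of the vehicle libraries ended both calls (adjusted p 0.058 to 0.073 for KLHDC7B and 0.051 to 0.060 for LAMP3). TAGLN, which ranged from 154 to 651 CPM in the vehicle libraries, lost its call without vehicle replicate 2 or 3 or any 1 of the treated libraries (adjusted p 0.051 to 0.13), and its log2 fold change was -0.90 without vehicle replicate 3.

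Of 34 mitosis genes measured, 29 fell and none rose (31 adjusted over the list alone; camera adjusted p = 1.1e-28, adjusted p = 0.080 with an estimated correlation). KIF20A, CDC20 and PLK1, which drive spindle function and mitotic exit, fell by 1.34, 1.26 and 1.21 on the log2 scale. Of 35 ribosome biogenesis genes 20 fell (26 adjusted over the list alone; adjusted p = 4.9e-16, and 0.083 with an estimated correlation), among them UTP20 (log2 fold change -1.34), LYAR (-1.24) and NOP56 (-0.99, SE 0.16). Of 29 replication-dependent histone genes 13 fell (23 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), with H2AC12 at -1.51 and H1-5 at -1.67, or -0.99 without vehicle replicate 3. Of 38 DNA replication genes 13 fell and 1 rose (20 and 1 adjusted over the list alone), and of 13 cytosolic heat shock genes 7 fell (7 over the list alone), led by HSP90AA1 (-1.26). Both lists passed camera, with an adjusted p = 0.33 and 0.14 with an estimated correlation. Without the shallow vehicle library and treated replicate 3 together, 16 mitosis, 10 ribosome biogenesis, 17 histone, 4 DNA replication and 3 heat shock genes fell. Without treated replicate 3 alone 18 mitosis, 8 ribosome biogenesis and 5 DNA replication genes fell. Without treated replicate 1 it was 12 ribosome biogenesis, 8 DNA replication and 5 histone genes, and without vehicle replicate 1 it was 8 DNA replication and 23 histone genes.

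Hypoxia response genes rose in 11 of 24 cases and fell in 1 (14 and 2 adjusted over the list alone; camera adjusted p = 1.5e-10, and an adjusted p = 0.15 with an estimated correlation). LOX, a collagen cross-linking enzyme, NDRG1 and BHLHE40 rose by log2 values of 2.64, 2.11 and 2.29. Autophagy genes rose in 14 of 40 cases with none falling (22 adjusted over the list alone; adjusted p = 4e-10, and 0.12 with an estimated correlation). RRAGD, a lysosomal GTPase of the mTORC1 pathway, rose from 3.77 ± 1.04 to 17.5 ± 2.93 CPM, the autophagosome protein gene WIPI1 from 12.3 ± 3.31 to 37.0 ± 3.01 CPM and the kinase gene ULK1 from 35.0 ± 7.32 to 105 ± 13.2 CPM. Of 37 ATF4 and amino acid response genes 13 rose and 1 fell (21 and 1 over the list alone; adjusted p = 7.9e-07, and 0.19 with an estimated correlation), including the glycine transporter gene SLC6A9 (1.46) and NUPR1 (2.81, or 3.45 without vehicle replicate 1). Without the shallow vehicle library and treated replicate 3 together, 8 of these genes rose and 1 fell, and without treated replicate 3 alone 8 rose, with 9 of the autophagy genes. DDIT3, a stress transcription factor of this list, stood at 22.2, 20.3 and 53.8 CPM in the treated replicates, and its call (log2 fold change 1.29) ended without replicate 3 (0.70, adjusted p = 0.080) or without vehicle replicate 1 or 2 (adjusted p 0.066 and 0.061).

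Of 37 lysosomal hydrolase genes 1 rose and 3 fell in rich medium, with CTSC, a dipeptidyl peptidase, at -1.12 (SE 0.18), and the counts were the same adjusted over the list alone (camera adjusted p = 0.87). This balance turned without vehicle replicate 2, where 7 rose and 1 fell, and without treated replicate 3 it was 1 and 1. Of 21 V-ATPase subunit genes, which encode the target of bafilomycin A1, 0 passed in the main edgeR fit over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called 2 (camera adjusted p = 0.92). Other edgeR fits called ATP6V0D1 without treated replicate 3 (0.53, adjusted p = 0.030) and with the replicate number as a block (0.41, adjusted p = 0.040). They called ATP6V1C2 without vehicle replicate 3 (1.96, adjusted p = 0.047), without treated replicate 1 (1.90, adjusted p = 0.039) and with the block (1.56, adjusted p = 0.0095). Of 25 cholesterol genes 2 rose, INSIG1 (1.17) and MVD (0.94), with 2 over the list alone, and the list did not pass (adjusted p = 0.13). MVD lost its call without vehicle replicate 1 or 2 or treated replicate 1 or 2 (adjusted p 0.052 to 0.11), and without treated replicate 3 the list had 4 genes rising. INSIG1 stood at 437, 481 and 221 CPM in treated replicates 1, 2 and 3, against 169 ± 9.27 CPM in vehicle. In the fixed panel SQSTM1, an autophagy receptor, rose by a log2 value of 1.00 (SE 0.19), VEGFA rose by 0.80 and ASNS by 0.70, while HMGCS1 (0.33), TFRC (-0.06), FTH1 (0.69), TXNIP (0.60) and VIL1 (-0.27) did not pass. TXNIP passed without treated replicate 3 (0.95, adjusted p = 0.023). FTH1 passed without vehicle replicate 3 (0.98, adjusted p = 0.025) and with the replicate number as a block (0.76, adjusted p = 0.0076). HMGCS1 (0.79, adjusted p = 0.032) and TXNIP (0.81, adjusted p = 0.044) passed without the shallow vehicle library and treated replicate 3 together. MKI67, a proliferation marker, fell by 1.03, a call that ended without vehicle replicate 1 or 2 or treated replicate 1 or 3 (adjusted p 0.067 to 0.12). Of 29 enterocyte genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 6.7e-05, and an adjusted p = 0.18 with an estimated correlation), among them ANPEP (1.53) and ALPI (1.43), and 4 rose without treated replicate 3, with or without the shallow vehicle library.

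Leaving out treated replicate 1, 2 or 3 reduced the calls in rich medium from 1971 to 1208, 1258 and 1018, and a fit of only the 6 libraries compared called 468. That fit ended the calls of SQSTM1 (adjusted p = 0.053) and ASNS (0.084), and of KLHDC7B, LAMP3, TAGLN, MVD, DDIT3 and MKI67 (0.053 to 0.14). Those of DDIT3 (0.16) and MKI67 (0.18) also ended without the shallow vehicle library and treated replicate 3. Of the lists past camera, 0 of 16 held with an estimated correlation, where 9 lists had an unadjusted p under 0.05, and fry called 11.

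Nutrient depletion in vehicle-treated cells, the next comparison, raised 2802 genes and lowered 2775. Among the lists 33 of 38 DNA replication, 33 of 34 mitosis, 15 of 19 glycolysis and 17 of 25 cholesterol genes fell, and 24 of 37 ATF4 and amino acid response genes rose. NPPB, the natriuretic peptide B gene, fell from 73.1 ± 27.3 to 3.99 ± 2.38 CPM (log2 fold change -4.21, SE 0.43, adjusted p = 3e-05) and DUSP6, a phosphatase that limits ERK signalling, from 90.6 ± 7.61 to 7.25 ± 0.790 CPM. NAV3, BTN1A1 and ANKRD1 fell by 3.91, 3.30 and 3.24 on the log2 scale. INHBE, an activin subunit, rose from 2.21 ± 0.260 to 44.1 ± 3.93 CPM and LAMP3 from 2.54 ± 0.592 to 70.8 ± 19.0 CPM. KLHDC7B, NIBAN1 and HSPA6 rose from means of 0.255, 0.352 and 0.299 CPM to 27.0, 17.3 and 9.08 CPM. HSPA6 lost its call without rich-medium vehicle replicate 2 or 3 (adjusted p 0.051 and 0.058), and NIBAN1 went from a log2 fold change of 5.34 to 6.38 without replicate 2.

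Of 38 DNA replication genes 33 fell and none rose (35 adjusted over the list alone; camera adjusted p = 7.5e-30, and an adjusted p = 0.15 with an estimated correlation). MCM10, RRM2 and UHRF1 fell by log2 values of -2.55, -2.29 and -2.07. Of 34 mitosis genes 33 fell (33 adjusted over the list alone; 2.1e-25, and an adjusted p = 0.15 with an estimated correlation), with ANLN at -1.81 and CDK1 at -1.66. Ribosome biogenesis genes fell in 30 of 35 cases (30 over the list alone; adjusted p = 0.15 with an estimated correlation), with LYAR at -2.03 and BOP1 at -1.67. In the glycolysis list 15 of 19 genes fell (15 over the list alone; adjusted p = 5.1e-12, and 0.23 with an estimated correlation). LDHA, which makes lactate, fell from 772 ± 92.9 to 121 ± 4.08 CPM, and the glucose transporter gene SLC2A1 and PFKP fell by 2.10 and 2.04 on the log2 scale.

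The ATF4 and amino acid response list had 24 of 37 genes rising and 1 falling (25 and 1 adjusted over the list alone; adjusted p = 5.3e-10, and 0.15 with an estimated correlation), with NUPR1 at 3.41 (4.05 without rich-medium replicate 1), DDIT4 at 2.61, SLC6A9 at 2.43 and DDIT3 at 2.31. Of 25 cholesterol genes 17 fell (20 over the list alone; 1.3e-07, and an adjusted p = 0.39 with an estimated correlation), including ACAT2 (-1.54) and EBP (-1.34). Nuclear-encoded respiratory chain genes fell in 25 of 51 cases (28 over the list alone; 3e-07, and an adjusted p = 0.56 with an estimated correlation), such as NDUFB3 (-1.37), with 13 falling without rich-medium replicate 3, 12 without depleted-medium replicate 1 and 16 without depleted-medium replicate 2. Autophagy genes rose in 18 of 40 cases (21 over the list alone; adjusted p = 0.33 with an estimated correlation), among them ULK1 (1.93). Endoplasmic reticulum chaperone genes rose in 9 of 21 cases (9 over the list alone; adjusted p = 0.56 with an estimated correlation), with HERPUD1 at 1.74. TXNIP, whose transcription follows glucose, fell from 28.4 ± 8.13 to 3.61 ± 0.544 CPM (log2 fold change -2.98, SE 0.34). In the intestinal stem cell list 12 of 19 genes fell (12 over the list alone; adjusted p = 0.15 with an estimated correlation), among them LGR5 (-1.83) and DKK1 (-1.81). Without any 1 library the count of calls lay between 3775 and 6103.

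Bafilomycin A1 and nutrient depletion, each against the same rich-medium vehicle libraries, moved many genes the same way. Of the calls, 912 genes were higher and 754 lower in both, and 11 went opposite ways, where independent lists of these sizes would share 172, 133 and 304. The log2 fold changes correlated at r = 0.756 across 18047 genes, which are not independent replicates. Unchanged groups simulated against shared controls gave a mean r = 0.545 (highest 0.577) and a covariance of 0.138 against the observed 0.589. They gave 0 shared calls, but groups without change yield few calls of any kind, so this 0 does not bear on the observed overlap. Part of the excess covariance can still come from the shared controls, since the simulated controls may vary less than the real ones. In differences of mean log2 CPM, another scale, the covariance was 0.508. There the observed variance of the controls alone would give 0.212. Without treated replicate 3 the correlation was 0.579, close to the highest simulated value, and 477 genes were higher, 290 lower and 38 opposite. The count lower in both was 419 without treated replicate 1 and 1137 without rich vehicle replicate 2, and without any 1 library other than treated replicate 3 the opposite genes numbered 4 to 9.

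**Figure D2:**
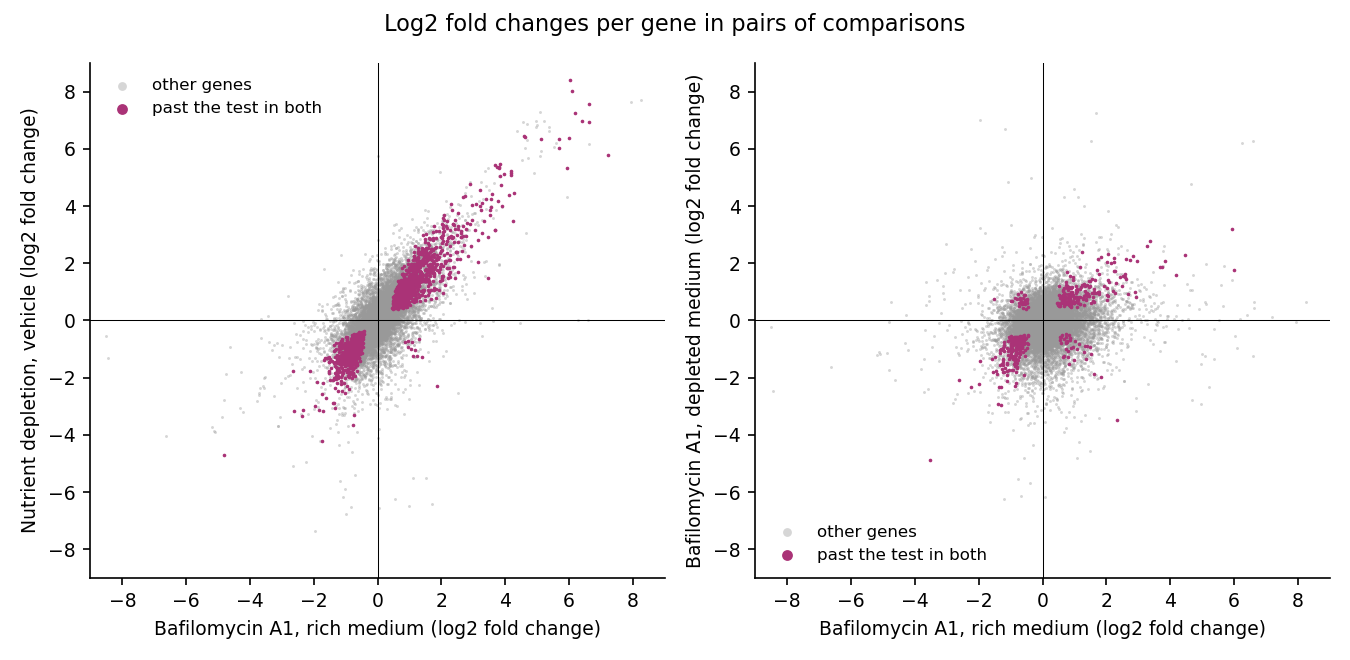
Log2 fold changes of the 18047 genes, with bafilomycin A1 in rich medium on both horizontal axes, nutrient depletion in vehicle-treated cells on the left vertical axis and bafilomycin A1 in depleted medium on the right one; coloured points passed the test in both comparisons. The left pair correlates at r = 0.756 and shares its control libraries, and the right pair correlates at r = 0.198 with none shared.

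In depleted medium bafilomycin A1 raised 992 genes and lowered 1066. Among the lists 14 of 25 cholesterol genes and 15 of 40 autophagy genes rose, and 14 of 34 mitosis genes fell. MFSD2A, a transporter of lysophospholipids (chromosome 1, 39955145 to 39969956), rose from 2.32 ± 0.528 to 16.9 ± 5.12 CPM (log2 fold change 2.87, SE 0.32, adjusted p = 0.00014), and SNPH, TMEM151A, HOXB9 and TMEM63C rose by log2 values of 2.61, 2.41, 2.35 and 2.20. ANXA8, an annexin that binds membrane phospholipids, fell from 8.82 ± 0.341 to 0.731 ± 0.283 CPM (-3.56, SE 0.28, adjusted p = 1.9e-05). PRSS35, CHI3L1, KCNJ16 and SIGLEC6 fell by 2.96, 2.93, 2.63 and 2.55 on the log2 scale, and without treated replicate 1 the log2 fold change of SIGLEC6 was -3.13.

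Of 25 cholesterol genes 14 rose and none fell (21 adjusted over the list alone; camera adjusted p = 3.1e-13, and an adjusted p = 0.31 with an estimated correlation). INSIG1, a sterol-responsive regulator of this pathway, rose from 82.1 ± 14.7 to 296 ± 24.8 CPM, and the mevalonate pathway genes MVD from 51.4 ± 0.991 to 149 ± 20.8 CPM and MVK from 15.4 ± 0.420 to 43.5 ± 2.59 CPM. HMGCS1 (0.69, adjusted p = 0.077) did not pass in edgeR with 12 libraries. It passed in DESeq2 (adjusted p = 0.036), in a fit of the 6 libraries compared (0.0056) and without the 2 libraries that stood apart in rich medium (0.0090). Fatty acid synthesis genes rose in 3 of 13 cases (7 over the list alone; 4.5e-05, and an adjusted p = 0.31 with an estimated correlation), with ACSS2 at 1.37 and ELOVL5 at 1.22. Of 40 autophagy genes 15 rose (17 over the list alone; 4.2e-09, and an adjusted p = 0.31 with an estimated correlation), with MAP1LC3B, which encodes the LC3B coat protein of autophagosomes, at 1.09 and ATG101 at 1.08. Mitosis genes fell in 14 of 34 cases (19 over the list alone; 1.1e-08, and an adjusted p = 0.37 with an estimated correlation), with CENPF at -1.22 and PTTG1 at -1.13. Without vehicle replicate 1 the counts were 6 cholesterol, 6 autophagy and 9 mitosis genes, and without vehicle replicate 2 they were 5 autophagy and 6 mitosis genes. Without treated replicate 2 it was 7 mitosis genes, and without treated replicate 3 they were 4 autophagy and 5 mitosis genes. The counts grew to 21 cholesterol, 17 autophagy and 17 mitosis genes without the 2 libraries that stood apart in rich medium.

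Of 19 intestinal stem cell and WNT target genes 4 fell (5 adjusted over the list alone; adjusted p = 0.00083, and 0.31 with an estimated correlation). CCND1, cyclin D1, fell from 141 ± 8.86 to 31.9 ± 5.67 CPM, and the WNT antagonist DKK1 from 504 ± 147 to 146 ± 17.0 CPM. Of 7 sterol efflux genes 2 fell, SMPDL3A (-1.02) and MYLIP (-1.01), with 4 over the list alone (adjusted p = 0.0054, and 0.31 with an estimated correlation). Lysosomal hydrolase genes rose in 1 and fell in 3 of 37 cases, the same counts over the list alone, with CTSC at -0.98 and CTSB at -1.06 (camera adjusted p = 0.010, and an adjusted p = 0.84 with an estimated correlation). That list did not pass without vehicle replicate 2 (adjusted p = 0.25). V-ATPase subunit genes rose in 2 of 21 cases (5 over the list alone; camera adjusted p = 0.37). It was 1 without vehicle replicate 2, and neither passed without vehicle replicate 1 or 3 or treated replicate 2 or 3. Without the 2 libraries that stood apart in rich medium 5 V-ATPase genes rose and 2 fell, 6 fatty acid synthesis genes rose, and 5 hydrolase genes fell. TXNIP rose by 1.40 from its low level in this medium, and its call ended without vehicle replicate 1 (1.28, adjusted p = 0.066). The calls in depleted medium fell from 2058 to 1042, 1046 and 1292 without vehicle replicate 1, 2 or 3, and to 1046 and 900 without treated replicate 2 or 3, while a fit of only these 6 libraries called 4218 and one without the 2 libraries that stood apart in rich medium called 3479. HOXB9 lost its call without vehicle replicate 1 or 2 or treated replicate 3 (adjusted p 0.059 to 0.071).

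Nutrient depletion under bafilomycin A1 raised 1893 genes and lowered 2459. CLDN2, a pore-forming tight junction protein, fell from 14.3 ± 5.79 to 0.530 ± 0.0749 CPM (log2 fold change -4.75, SE 0.39, adjusted p = 6.6e-06), the adhesion genes CEACAM6 and CEACAM1 by 4.69 and 4.05, and SIGLEC6 and the amino acid transporter gene SLC7A8 by 3.92 and 3.81 on the log2 scale. INHBE rose from 14.6 ± 12.7 to 190 ± 33.2 CPM, and SNPH, ASPA and BIRC7 by log2 values of 2.90, 2.78 and 2.60. Without rich-medium replicate 3 the log2 fold changes were 4.71 for INHBE (3.71 with it), 3.95 for ASPA and 5.00 for KLHDC7B, and without depleted-medium replicate 1 that of SIGLEC6 was -4.50. KLHDC7B was called at 2.86, a call that ended without rich-medium replicate 1 or 2 or depleted-medium replicate 2 or 3 (adjusted p 0.073 to 0.092) and in a fit of the 6 libraries compared (0.13).

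Glycolysis genes fell in 18 of 19 cases (18 adjusted over the list alone; camera adjusted p = 1.4e-20, and an adjusted p = 0.23 with an estimated correlation), with SLC2A1 at -3.12, LDHA at -2.88 and SLC2A3 at -2.75. DNA replication genes fell in 29 of 38 cases and mitosis genes in 26 of 34 (34 and 29 over the list alone; both an adjusted p = 0.23 with an estimated correlation), with RRM2 at -3.06 and PTTG1 at -1.81. WNT target and stem cell genes fell in 12 of 19 (14 over the list alone; adjusted p = 0.23 with an estimated correlation), with CCND1 at -3.51. Endoplasmic reticulum chaperone genes rose in 13 of 21 (16 over the list alone; 5.9e-08, and an adjusted p = 0.43 with an estimated correlation), including SEL1L (1.61) and HSPA5 (1.60), which encodes the chaperone BiP. Hypoxia response genes rose in 1 and fell in 13 of 24 (2 and 14 over the list alone; 0.00020, and an adjusted p = 0.49 with an estimated correlation), with PLOD2 at -2.22, and 7 fell without rich-medium replicate 2. The 4352 calls fell to 2727 and 2376 without rich-medium replicate 1 or 2 and to 2803 without depleted-medium replicate 2.

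The interaction asked whether the bafilomycin A1 response differed between the media, and 424 genes responded more positively and 692 more negatively in depleted medium. The ribosome biogenesis list differed most by camera. Of its 35 genes 16 had a higher response in depleted medium and none a lower one (24 adjusted over the list alone; adjusted p = 3.2e-19, and 0.11 with an estimated correlation). RRP12 differed by 1.95 (SE 0.29), POLR1B, a subunit of RNA polymerase I, by 1.48 (SE 0.22) and GAR1 by 1.59 (SE 0.38). RRP12 stood at 91.9 ± 28.9 and 62.8 ± 10.1 CPM in rich vehicle and bafilomycin A1 libraries and at 49.1 ± 7.94 and 129 ± 13.7 CPM in depleted ones. The list's median response was -0.63 in rich and 0.23 in depleted medium. The count of 16 became 9 without rich bafilomycin A1 replicate 3, 7 and 10 without depleted vehicle replicate 1 or 3, 10 and 9 without depleted bafilomycin A1 replicate 2 or 3, and 11 without the 2 libraries that stood apart in rich medium.

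Enterocyte genes showed the opposite interaction, with 10 of 29 lower and none higher (14 adjusted over the list alone; adjusted p = 7.8e-08, and 0.15 with an estimated correlation). The count of 10 became 4 without the 2 libraries that stood apart, 5 without rich bafilomycin A1 replicate 2, 3, 5 and 3 without depleted vehicle replicate 1, 2 or 3, and 3 and 2 without depleted bafilomycin A1 replicate 2 or 3. CDX2, an intestinal transcription factor, stood at 70.8 ± 29.9 CPM with vehicle and 142 ± 29.3 CPM with bafilomycin A1 in rich medium, and at 135 ± 17.5 and 80.4 ± 8.09 CPM in depleted medium (interaction -1.74, SE 0.35, adjusted p = 0.011). The aminopeptidase gene ANPEP differed by -1.87 and LCT, lactase, by -2.88. Among hypoxia response genes 5 of 24 differed downwards and 1 upwards (6 and 1 over the list alone; 0.0055, and an adjusted p = 0.68 with an estimated correlation), with NDRG1 at -1.99, and the list did not pass without rich-medium bafilomycin A1 replicate 2 (adjusted p = 0.10). Without any 1 library other than rich vehicle replicate 2 or 3 or rich bafilomycin A1 replicate 3, the count of 5 became 1 to 3. Among called genes with a mean of at least 5 CPM, HSPA4L, MFSD2A, FJX1 and POLR3G had the highest differences besides RRP12 (2.27, 2.26, 2.14 and 1.98), and CYP2W1, ANXA8, PTH1R, TFEC and ALPP the lowest (-3.83, -3.62, -3.34, -3.17 and -2.82).

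Some interaction values moved when 1 library was left out. TFEC stood at 11.4, 13.5 and 53.1 CPM in rich-medium bafilomycin A1 replicates 1, 2 and 3, differed by -2.11 without replicate 3, and lost its call without depleted vehicle replicate 3 or depleted bafilomycin A1 replicate 2 or 3 (adjusted p 0.051 to 0.060). CYP2W1 differed by -3.10 without rich-medium bafilomycin A1 replicate 3. PTH1R lost its call without any 1 of the 12 libraries other than rich vehicle replicate 3 (-4.28) and rich bafilomycin A1 replicate 1 (adjusted p 0.053 to 0.099), and differed by -2.48 without rich bafilomycin A1 replicate 3. GAR1 lost its call without rich bafilomycin A1 replicate 3, depleted vehicle replicate 1 or 3 or depleted bafilomycin A1 replicate 3 (adjusted p 0.057 to 0.070), and POLR3G without depleted vehicle replicate 1 or 2 or depleted bafilomycin A1 replicate 3 (adjusted p 0.055 to 0.063). LCT lost it without rich bafilomycin A1 replicate 2, any 1 of the depleted vehicle libraries or depleted bafilomycin A1 replicate 2 or 3 (adjusted p 0.052 to 0.071), and differed by -3.49 without depleted bafilomycin A1 replicate 1. ANPEP lost it without depleted vehicle replicate 1 or 3 or depleted bafilomycin A1 replicate 2 or 3 (adjusted p 0.050 to 0.054). Without the 2 libraries that stood apart in rich medium POLR3G, PTH1R, GAR1 and ANPEP lost their calls (adjusted p 0.054 to 0.13). The 1116 calls became 397, 594 and 516 without depleted vehicle replicate 1, 2 or 3, 439 and 452 without depleted bafilomycin A1 replicate 2 or 3, 676 and 618 without rich bafilomycin A1 replicate 2 or 3, and 1893 without rich vehicle replicate 2.

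**Figure D3:**
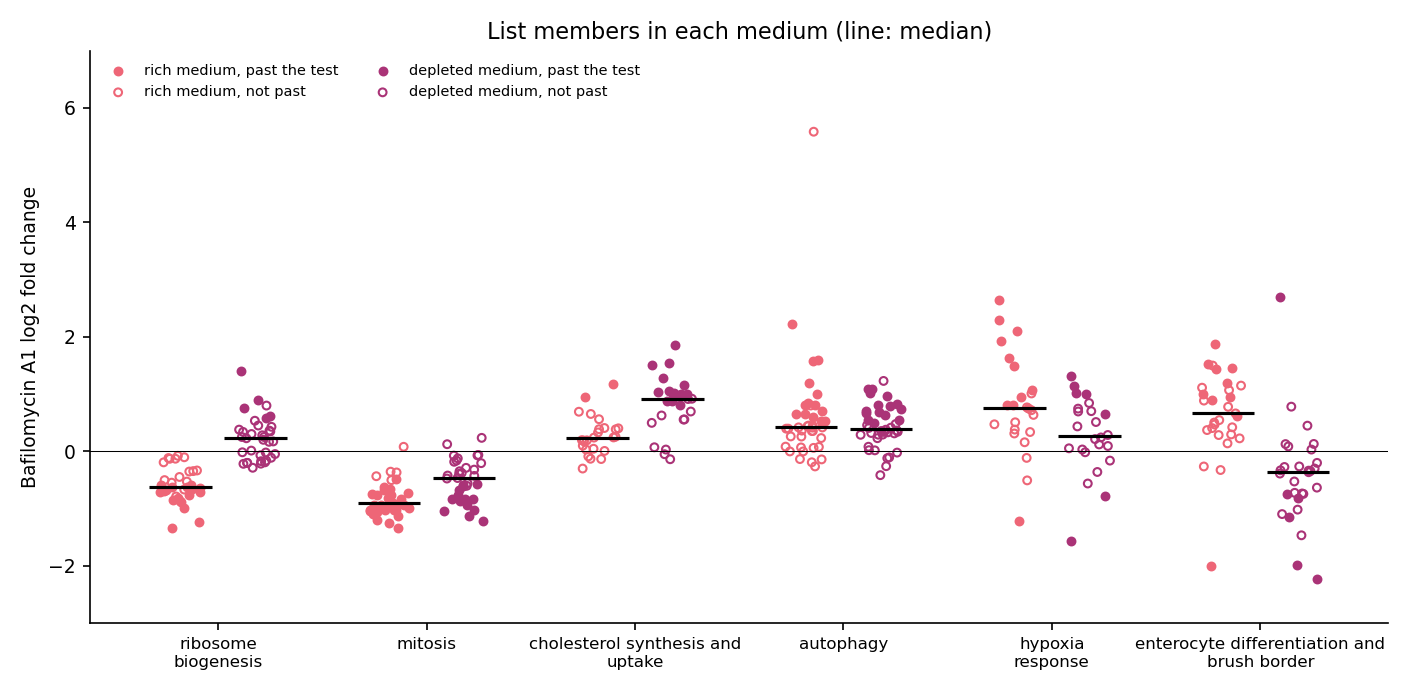
Log2 fold change of bafilomycin A1 against vehicle for each member of 6 gene lists, in rich and in depleted medium; filled points passed the test over all genes, open points did not, and the line is the list's median. Ribosome biogenesis genes have a median of -0.63 in rich and 0.23 in depleted medium, and enterocyte genes 0.66 and -0.37.

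Across genes the bafilomycin A1 responses in the 2 media, which share no library, correlated weakly (r = 0.198, rho = 0.192; genes are not independent replicates). In both media 183 genes rose and 178 fell, where independent lists would share 61.0 and 50.9, and 65 went opposite ways against 113. Without rich bafilomycin A1 replicate 1, 2 or 3 the shared genes were 115, 126 and 155 rising and 95, 118 and 111 falling, with 34, 28 and 31 opposite. Without depleted vehicle replicate 1, 2 or 3 they were 86, 86 and 112 rising and 111, 108 and 134 falling, with 14, 32 and 25 opposite. Without depleted bafilomycin A1 replicate 1, 2 or 3 they were 124, 93 and 91 rising and 138, 110 and 110 falling, with 34, 20 and 21 opposite, and without rich vehicle replicate 2 or 3 the opposite genes numbered 125 and 103. Of 6 leukocyte genes 1 rose with bafilomycin A1 in rich medium, CSF1R (1.58), and edgeR called 0 in depleted medium with 12 libraries (1 at an unadjusted p under 0.05, and 0 by DESeq2). There CD14 fell in a fit of the 6 libraries compared (-0.77, adjusted p = 0.040) and without the 2 libraries that stood apart in rich medium (-0.78, adjusted p = 0.031). Of 6 goblet cell genes edgeR called 0 with bafilomycin A1 in rich medium (2 at an unadjusted p under 0.05, and 2 by DESeq2) and 1 fell in depleted medium, a call that held only without treated replicate 1 when 1 library was left out. Of 5 enteroendocrine genes it called 0 in either medium (1 and 0 at an unadjusted p under 0.05, and 0 by DESeq2). Of 7 fibroblast genes it called 0 in rich medium (2 at an unadjusted p under 0.05, and 1 by DESeq2), and PDGFRB fell by 2.37 in depleted medium, where the list passed camera (adjusted p = 0.028, and an adjusted p = 0.31 with an estimated correlation) but not without vehicle replicate 2 (adjusted p = 0.092). COL5A1 of this list also fell there in a fit of the 6 libraries compared (-0.97, adjusted p = 0.040). In rich medium PDGFRA of this list fell in edgeR without vehicle replicate 3 (-1.19, adjusted p = 0.025) and with the replicate number as a block (-0.90, adjusted p = 0.0018).

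**Figure D4:**
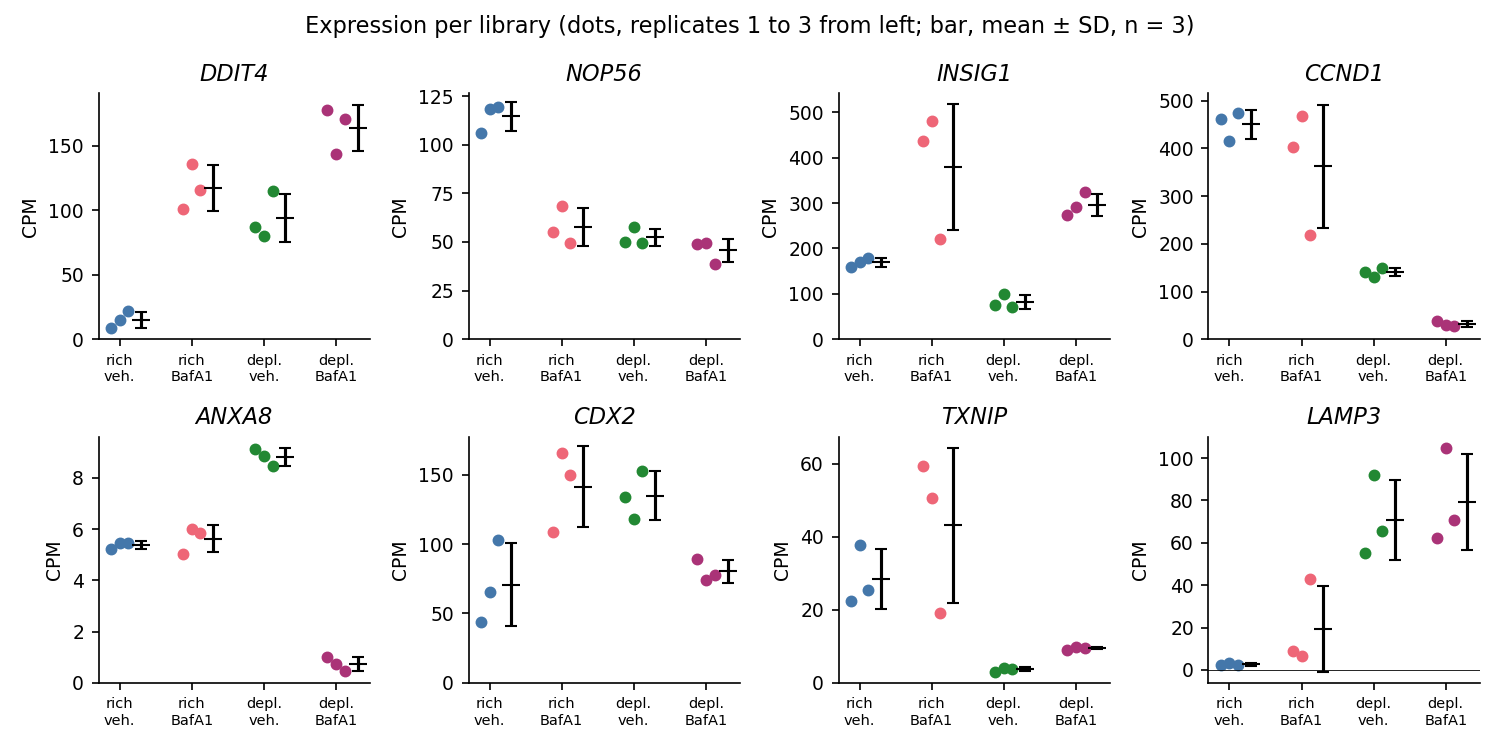
TMM-scaled CPM of 8 genes in each of the 12 libraries (dots, replicates 1 to 3 from left to right within a group) with the group mean ± SD (n = 3). DDIT4 is higher with bafilomycin A1 in rich medium, ANXA8 and CCND1 are lowest in depleted medium with bafilomycin A1, and LAMP3 in rich-medium bafilomycin A1 ranges from 6.43 to 42.8 CPM.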

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

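The tests of samples held out of the depletion score, the covariances with unshared controls, the tests of scaling and gene length and the fits without 2 libraries were chosen only after the results were seen. The bafilomycin A1 response differed between the media, by the interaction test, in 1116 genes and 14 gene lists. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), and fry called 3. Of 60 splits of the libraries 2, the real one included, gave as many genes. Most splits mix treated and vehicle libraries within a medium, which puts the treatment response into the spread between replicates. Their low counts are then largely fixed in advance, so the splits cannot exclude chance. The highest other split gave 2894 genes. It keeps the rich-medium groups and exchanges the treatments in depleted medium, so it measures the sum of both responses, a structure of the samples. For the other 4 comparisons 1 of 10 splits, the real one, gave as many genes, with real counts of 1971, 5577, 2058 and 4352 and highest others of 1, 0, 0 and 0; 10 splits are too few for a share under 0.05.

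Among the named genes the response was more negative in depleted medium for CYP2W1 (-3.83), ANXA8 (-3.62), PTH1R (-3.34), TFEC (-3.17), LCT (-2.88), ALPP (-2.82), PDGFRB (-2.69), SIGLEC6 (-2.57), CLDN2 (-2.48), IFIT3 (-2.16) and DDIT4 (-2.13). It was also lower for NDRG1 (-1.99), LOX (-1.95), CSF1R (-1.93), KCNJ16 (-1.93), CA12 (-1.91), YPEL2 (-1.89), ANPEP (-1.87), CCND1 (-1.83), AKR1C1 (-1.77), CDX2 (-1.74), UBE2L6 (-1.74), PRSS35 (-1.66) and SLC2A3 (-1.66). Smaller negative differences were those of APOC3 (-1.59), APOA1 (-1.56), CHI3L1 (-1.54), GDF15 (-1.53), MYO1A (-1.49), TP53INP1 (-1.43), SMPDL3A (-1.32), PLOD2 (-1.31), CTSB (-1.04) and ULK1 (-0.91). AKR1C1 and ALPP have close copies that share reads. Leaving out 1 library ended calls of LOX (adjusted p up to 0.080), CA12 (up to 0.10), UBE2L6 (up to 0.075), SLC2A3 (up to 0.12), CTSB (up to 0.12) and ULK1 (up to 0.092), and that of SMPDL3A without depleted bafilomycin A1 replicate 2 (0.052). Without the 2 libraries that stood apart LOX, SLC2A3, CTSB and ULK1 (adjusted p 0.065 to 0.083) lost their calls, beside those given in the results.

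The response was more positive in depleted medium for HSPA4L (2.27), MFSD2A (2.26), FJX1 (2.14), POLR3G (1.98), RRP12 (1.95), LEF1 (1.75), AEN (1.65), GAR1 (1.59), POLR1B (1.48) and EGLN3 (1.44). It was also higher for HSPH1 (1.35), NOLC1 (1.31), UTP20 (1.23), BOP1 (1.19), SQLE (1.15), HSP90AA1 (1.09), ATF3 (1.07), CDC20 (0.97), BUB1 (0.82) and NOP56 (0.79). Leaving out 1 library ended the calls of BUB1 and SQLE in 10 and 8 cases, with adjusted p up to 0.093 and 0.12. Calls of HSP90AA1 and LEF1 ended in 5 and 4 cases (adjusted p up to 0.090 and 0.069), and those of CDC20 (0.061) and ATF3 (0.053) without depleted vehicle replicate 1. SQLE (0.090), BUB1 (0.083) and HSP90AA1 (0.059) also lost theirs without the 2 libraries that stood apart.

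Replicate 3 of the rich-medium bafilomycin A1 group lay near the depleted-medium vehicle libraries. Its bafilomycin A1 score exceeded the highest of those libraries by 0.0939 log2 units, less than their own range of 0.137, so a wrong label cannot be told apart from a true label by this score. On a depletion score it lay 0.225 to 0.321 below the lowest of them, against at most 0.155 for any of them held out in turn. If it were a mixture of both kinds of RNA, the mixing fraction would be the same for genes higher and lower in depleted-medium vehicle; the medians were 0.595 and 0.685, a difference of -0.0894 (bootstrap interval -0.111 to -0.0721). That is not 0 and is below the 0.2 set as the bound, so a mixture may be the source and stays open, as does a culture short of nutrients, which was not tested.

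Of the calls for bafilomycin A1 in rich medium and for nutrient depletion, 912 genes were higher and 754 lower in both, or 477 and 290 without treated replicate 3, while the lower ones were 419 without treated replicate 1 and 1137 without rich vehicle replicate 2. In differences of mean log2 CPM, a scale other than the fitted fold changes and simulated controls of the results (0.589 and 0.138), the covariance was 0.508 against 0.212 expected from the observed variance of the shared controls. The ratio was 2.39, or 1.94 without treated replicate 3 and 2.50 without the shallow vehicle replicate 1. With controls not shared, the covariance was 0.201 to 0.399, and 0.114 to 0.290 without treated replicate 3, and these values argue against shared controls, treated replicate 3 alone or the shallow library as the whole cause. No biological explanation was tested beyond the 2 treatments that the design names, which stay open.

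Of 35 ribosome biogenesis genes 20 fell with bafilomycin A1 in rich medium (8 without treated replicate 3 and 12 without treated replicate 1), and 16 passed the interaction test (7 to 10 without rich bafilomycin A1 replicate 3, depleted vehicle replicate 1 or 3 or depleted bafilomycin A1 replicate 2 or 3). The list lost both its calls with an estimated correlation (adjusted p = 0.083 and 0.11). Its median interaction was 0.79 on the log2 scale, 0.85 without the shallow vehicle library, 0.71 without treated replicate 3 and 0.75 without both, with a spread near 0.100. The median exceeded that of the genes tested by 0.85. An error of scaling would shift genes alike and cancels in this difference, so the list differed from the typical gene under any scaling. TMM scaling holds the median of the genes tested near 0 (-0.0544). The difference thus had to lie near the list's own median, and it cannot test whether scaling shifted that median. After removal of the trend with gene length the list's median was 0.90. These values argue against either library or gene length as the whole cause. The difference between the media that the design names stays open as an untested explanation.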

How the results depend on the processing

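Fits without the 2 libraries that stood apart were chosen after seeing the data; all other alternatives were planned. The balance of lysosomal hydrolase genes in rich medium turned from 1 rising and 3 falling to 7 and 1 without vehicle replicate 2. Scaling by DESeq2 size factors, the series-wide count table and removal of mitochondrial and small RNA genes kept every count of genes within 1.5 times. In the order rich bafilomycin A1, depletion, depleted bafilomycin A1, depletion under bafilomycin A1 and interaction, a minimum fold of 1.5 left 213, 1890, 262, 1104 and 139 genes, since it asks for larger changes. Fits of the 6 libraries compared gave 468, 3684 and 4218 in the first 3. The DESeq2 test gave 2990 for rich bafilomycin A1 and 2093 for the interaction, and no low-count filter 1792 for the interaction. Without the 2 libraries rich bafilomycin A1 gave 1052 and depleted bafilomycin A1 3479. Leaving out 1 library gave 1018 to 2695, 3775 to 6103, 900 to 1475, 2376 to 4610 and 397 to 1893 genes. With an estimated correlation 0, 0, 0, 0 and 0 lists passed camera (9, 7, 4, 7 and 3 at an unadjusted p under 0.05). Fry called 11, 18, 10, 15 and 3. The correlation of both bafilomycin A1 responses was 0.0624 with no filter, 0.245 in genes of at least 5 CPM, 0.237 without the 2 libraries and 0.148 to 0.229 leaving out 1. That of rich bafilomycin A1 and depletion was 0.608, 0.792, 0.575 and 0.579 to 0.835 under the same settings. The bound for a moved correlation was narrowed to the spread of the leave-one-out values after these were seen. Settings that test larger changes or fewer samples can lower a count, but fewer samples raised depleted bafilomycin A1 from 2058 to 4218 and 3479. The fit of all 12 libraries shares its estimate of the spread between the media. Rich vehicle libraries correlated with each other at 0.946 to 0.954, and depleted vehicle ones at 0.977 to 0.989. The similar counts of both bafilomycin A1 comparisons in that fit became 468 and 4218 in fits of 6 libraries. The cause was not tested. The shallow library limits genes near 0.0771 CPM, the level of 1 read in it.

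With the replicate number as a replicate block the counts were 2832, 6504, 3014, 5319 and 1969. These exceed the counts without the block in each comparison. The samples were not taken as paired: of 18 same-numbered pairs 6 correlated above 0.1, and 10 of 12 libraries correlated best with their own number, a hint from the data and not the design. The 6 were all the pairs of replicates 2 or of replicates 3 among rich vehicle, depleted vehicle and depleted bafilomycin A1 libraries (0.209 to 0.294). Small RNA made up 8.12% to 9.12% of the reads in the replicate 3 libraries of all 4 groups. In the other libraries it was 2.30% to 6.42%. A shared effect of replicate number is thus possible, for replicate 3 in all 4 groups, and the main counts leave it out.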

Other observations

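Gene families grouped by the stem of their symbols were tested after seeing the data, with camera over 143 families of at least 12 genes. In depleted medium bafilomycin A1 lowered 7 of 14 annexin genes and raised none, and this family stood first (camera adjusted p = 1e-09, and an adjusted p = 0.022 with an estimated correlation). Beside ANXA8 and its near-identical copy ANXA8L1, which share reads, ANXA3 fell by 1.47, ANXA2 by 0.90, ANXA11 by 0.85 and ANXA4 by 0.82 on the log2 scale. Without each of the 6 libraries in turn 5 to 7 annexin genes fell, and the adjusted p with an estimated correlation ranged from 0.042 to 0.071, ending that call without vehicle replicate 3 (0.071) or treated replicate 1 or 2 (0.053 and 0.057). The adjustment covered the 143 families of 1 comparison, not all 5 comparisons. Annexin genes also fell elsewhere, in 9 of 14 cases with depletion under bafilomycin A1, where none rose. With bafilomycin A1 in rich medium 4 fell and 1 rose, and with depletion 5 fell and 3 rose. Most genes named SEC encode coat proteins of transport vesicles or parts of the translocon. With bafilomycin A1 in depleted medium 9 of 30 of them rose (camera adjusted p = 0.00029, and 0.40 with an estimated correlation), led by SEC23IP (1.11), SEC24A (1.08) and SEC24D (0.91).

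Semaphorin genes fell in 8 of 17 cases and rose in 1 with bafilomycin A1 in depleted medium (camera adjusted p = 0.0014, and an adjusted p = 0.59 with an estimated correlation), with SEMA5A at -2.31 and SEMA7A at -1.53. Nucleoporin genes fell in 7 of 22 cases with bafilomycin A1 in rich medium and in 14 of 22 with nutrient depletion (adjusted p = 0.40 and 0.68 with an estimated correlation). Genes of the CCT chaperonin and others with its stem fell in 7 of 12 cases with depletion, with CCT5 at -1.43, and 1 rose, the low-level CCT6B (2.47), with a camera adjusted p = 0.039 and an adjusted p = 0.79 with an estimated correlation.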
